A study of Mus musculus with 10 samples.

How the data were processed

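Skin of 10 male C57BL/6 mice was profiled by RNA sequencing, with 5 mice in each of 2 age groups. The labels and titles of the individual samples give the ages as 9 and 24 months, whereas the design text of the series gives the younger group as 2 months. The groups were named by the sample labels, and no measurement used here settles which age is right, so every statement on the younger mice carries this doubt. Replicates were numbered 1 to 5 within each age in the order in which they are listed. Each title carries its own number, which was read as 1 animal per library. The labels do not state this in words; if any libraries shared an animal, the p-values would measure only the spread between those libraries. The body site, the hour of collection, the hair cycle stage, and the dates of dissection and sequencing are not given in the sources used here.

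RNA was prepared with an Illumina kit for multiplexed mRNA libraries, per the labels. Per the submitters' processing notes, CASAVA 1.7, STAR 2.4.1d and featureCounts 1.4.6-p4 were used with the mouse genome build GRCm38. The notes give these names without their roles. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Genes that share sequence with near-identical copies, such as the globin, class I histocompatibility and immunoglobulin families, and genes that overlap another gene are therefore uncertain.

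The deposited count table holds whole-number read counts for 47729 Ensembl genes in the 10 libraries, not normalised. A symbol was found for 47224 of the identifiers, and the 505 others held at most 0.0668% of the counts of a library. Coordinates were taken from the GENCODE vM21 annotation of GRCm38, matched by identifier; this is the same build, but not necessarily the release the submitters used. Total counts ranged from 29.3 to 56 M per library, where M stands for mega. Xist reached at most 0.421 CPM, the count scaled to a common library size, and Ddx3y was at least 55.1 CPM. The counts of every pair of libraries differed by more than sampling noise, with a chi-square per gene of at least 32.7, so that no pair looked like 1 library deposited again. This check cannot show that the libraries came from separate animals, which rests on the titles.

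A second deposited table is named RPKM by the authors, but its values are not divided by the total of their own column. Over 8455 genes with more than 200 counts and more than 3 units in every library, each value equalled the count divided by a gene length and by 1 of 40 totals, taken in turn down the rows and on through the columns. The residual SD on the log2 scale was 3.66e-05 with this rule and 0.434 with the libraries' own totals. The first 10 of the 40 totals matched the totals of these libraries within 0.000243%, and 2.49% of the values were divided by their own library's total. Divisors lay between 0.335 and 1.91 times the library's own total, so that the values of 1 gene are distorted between libraries by up to 4.59-fold. The count table was therefore the basis of every result, and the RPKM values were used only as an alternative, both as deposited and after rescaling each value to its own library's total.

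Genes were kept by the filterByExpr function of edgeR 4.0.16, which left 17668 genes, and libraries were scaled by the trimmed mean of M values. The main test was edgeR's robust quasi-likelihood F test of 24 against 9 months, with no covariate and Benjamini-Hochberg adjustment over the genes tested. An adjusted p under 0.05 counted as a call. Log2 fold changes are for 24 months over 9 months, and their SE was derived from the F statistic. Levels are CPM after scaling, given as mean ± SD of the 5 mice. R 4.3.3 was used with limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

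The test, the covariates, the rule for named genes and 52 gene lists were fixed before the data were examined. The lists cover the matrix, hair follicle, epidermis, lipids, other cell types of skin, immune cells, ageing, growth signals, metabolism, stress and RNA quality. Each list was tested with camera from limma on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 52 lists, and again with an estimated correlation, with fry and by an exact permutation of the animals' list means. The median fold change of a list and its counts come from the edgeR fit. For each list, calls adjusted over the list alone are given beside those over all genes.

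The rule for named genes had 3 parts. The first took the 10 largest changes in each direction among genes with an adjusted p under 0.05, a mean of at least 1 CPM and non-overlapping groups; it left out predicted genes, receptor segments and pseudogenes and allowed at most 3 members of any list. That part named 0 genes, because no gene was called. The second took up to 4 members with the smallest adjusted p from each list described, whatever their direction. The third always named 10 genes, namely Cdkn2a, Cdkn1a, Col1a1, Col3a1, Krt14, Acta1, Adipoq, Igkc, C4b and Ptprc. Any other gene is marked as chosen after its values were seen. Some genes that the rule selects are not reported here.

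Spread within an age was the root mean square distance of a mouse's log2 CPM from the mean of its group over the 1000 genes most variable within groups. Single values per mouse were compared by two-sided exact permutation tests over the 252 ways of assigning the mice, whose smallest possible p is 0.00794. Alternatives comprised other scalings, filters and tools, covariates from hair, muscle and fat genes, 1 surrogate variable, the RPKM table and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out the 9 months replicates 4 and 5 together, with or without the muscle covariate, leaving out 24 months replicates 1 and 2, with or without 9 months replicate 1, the RPKM values rescaled to own totals, and the permutation of list means. Random splits of the 10 libraries into 5 and 5 were refitted 100 times with edgeR and camera and 60 times with DESeq2, the real split included.

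The gene test was tried on simulated data for 24 against 9 months. Counts for 17668 genes were drawn from the observed means, library sizes and dispersions, with 200 genes changed. It called 33 of 67 genes changed 2-fold, 58 of 67 changed 4-fold and 64 of 66 changed 8-fold, each in the right direction, besides 7 unchanged genes. In a separate simulation, camera called the 1 list shifted 1.5-fold and 0 of the 52 unchanged lists. Genes were drawn independently in both simulations, unlike genes in tissue. Differences that many genes of a library share were therefore absent, and the shares found may not hold for the real libraries.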

Results

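Messenger RNA levels were measured in skin of 5 male C57BL/6 mice labelled 9 months old and 5 labelled 24 months old. Skin can hold epidermis, hair follicles, dermis, fat, a thin sheet of muscle, vessels, nerves and immune cells, so a level can differ through the cells present as well as through their activity. Total counts were 39.0 ± 10.7 M per library at 9 months and 37.0 ± 3.63 M at 24 months (SD, n = 5 each). The difference of -1.98 M was within the spread between libraries by a two-sided exact permutation test (p = 0.778), and it was 2.27 M in the other direction without 9 months replicate 5, the deepest library at 56 M. The series' own design text gives the younger age as 2 months, which bears on every comparison below.

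The comparison addresses how the skin transcriptome differs between the age groups. As groups, genes of B cells, T cells, neutrophils and the interferon response were higher at 24 months, with median log2 fold changes of 2.30, 0.77, 2.26 and 1.04, and clock genes by a median of 0.46 (adjusted p = 0.235 to 0.314 with an estimated correlation between genes). Genes of growing hair, cell division and collagen were lower, with medians of -7.13, -0.93 and -0.69 (adjusted p = 0.314 to 0.346 with an estimated correlation). None of these calls held with the estimated correlation; they rest on a set test with an assumed one, and that of growing hair rests mainly on 2 young mice, without which the median for cell division was -0.40. Without 24 months replicates 1 and 2, the medians were 1.08 for B cells, -0.31 for collagen and 0.26 for clock genes. No single gene passed the threshold, however. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 17668 genes were called higher and 0 lower at 24 months; the smallest adjusted p was 0.0909. At an unadjusted p under 0.05 there were 1169 higher and 1139 lower genes, 2308 in all, where 883 would pass if no gene differed. Other splits of the 10 libraries into 5 and 5 gave a median of 956 and up to 2386. With 9 months replicates 4 and 5 on the same side, as in the real split, their median was 1368. The 2 ages did not overlap for 510 genes, or 2.89%, against 0.794% on average over all possible splits. DESeq2 called 433 genes higher and 483 lower from the same counts before the filter; it gave an adjusted p to 19973 genes and none to 11300 others, 103 of them as outliers by Cook's distance. From the filtered counts, limma-voom called 0 and 0, and limma with library quality weights 3 and 0. Without 24 months replicate 4 the edgeR test called 8 higher, among them Hdc, Ccl8 and Iigp1. The 3 genes with an adjusted p under 0.1 in the edgeR test were Fam107a, Aox3 and S100a9, the same 3 that the quality-weighted test called, and the first 2 of them were chosen after their values were seen. Fam107a, encoding an actin-associated protein (ENSMUSG00000021750, chromosome 14, 8296274 to 8318023, minus strand, GRCm38), stood at 2.10 ± 0.323 CPM at 9 months and 5.71 ± 1.02 at 24 months, a log2 fold change of 1.44 ± 0.20 (SE, n = 5 each). Aox3, an aldehyde oxidase (ENSMUSG00000064294, chromosome 1, 58113130 to 58200698, plus strand), stood at 5.36 ± 0.464 and 11.4 ± 1.45 CPM.

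Among the 52 fixed gene lists, camera with a preset correlation of 0.01 called 13 higher and 12 lower at 24 months. None of the 25 calls held with an estimated correlation, where the smallest adjusted p was 0.235. The list statements that follow therefore rest on the preset value. An exact permutation of list means gave 0 calls after adjustment, and fry gave 1, the neutrophil list. The permutation left little room for a call. Even lists at its smallest possible p of 0.00794 had an adjusted p of 0.059.

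B cell and plasma cell genes were higher at 24 months, with a median log2 fold change of 2.30 over 25 tested members, 23 of them positive (camera adjusted p = 1.99e-10; adjusted p = 0.235 with an estimated correlation). Adjusted over the list alone, 15 members rose and 0 fell in the edgeR test, against 0 over all genes tested. Igkc, the kappa light chain constant region (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966, plus strand), stood at 36.7 ± 28.0 CPM at 9 months and 276 ± 197 at 24 months, a log2 fold change of 2.91 ± 0.67 (SE, n = 5 each; edgeR adjusted p = 0.163). Its levels overlapped, at 75.8 and 74.2 CPM in 24 months replicates 4 and 5 and 81.5 CPM in 9 months replicate 4. Blk, a kinase of B cells, rose by 3.06, Cd79a, part of the B cell receptor, by 2.89, and Irf4, a transcription factor of plasma cell formation, by 1.24 on the log2 scale, all adjusted over the list alone. Blk stood at 32 CPM in 24 months replicate 1, at 1.44 to 10.9 CPM in the other older mice and at 0.853 to 1.84 CPM in the young ones, and Cd79a at 44 against 1.73 to 12.2 and 1.15 to 3.6 CPM. For both genes 24 months replicate 5 lay within the young range. The same library, 24 months replicate 1, stood apart in white adipocyte genes, with a list mean of 9.42 log2 CPM against 6.78 to 7.77 in the 9 others. Leaving it out, the log2 fold change of Blk was 2.24 and the log2 fold change of Cd79a was 2.00. Without 24 months replicates 1 and 2, the list median was 1.08 and 9 members rose.

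Genes of T cells and cytotoxic lymphocytes had a median log2 fold change of 0.77, and 27 of 28 members were positive (camera adjusted p = 2.09e-16; adjusted p = 0.235 with an estimated correlation). Adjusted over the list alone, 15 members rose, and the list mean of each 24 months mouse lay above that of every 9 months mouse. Eomes, a transcription factor of cytotoxic cells, rose by 2.91, Cd2, an adhesion molecule of T cells, by 1.42, and Il2rb, an interleukin receptor chain, by 1.18. Eomes was near the floor, at 0.035 to 0.157 CPM in the young mice and 0.285 to 2.06 CPM in the older ones. Its log2 fold change was between 0.29 and 3.56 over the alternatives. Without the 9 months replicates 4 and 5, 9 members rose. The gamma-delta T cells of the epidermis had a median of 0.14 over 10 members and were not called (camera adjusted p = 0.497). Ptprc, the common leukocyte antigen CD45 (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708, minus strand), stood at 45.4 ± 9.17 and 85.9 ± 34.8 CPM (edgeR adjusted p = 0.164).

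Neutrophil genes had a median of 2.26 over 7 tested members (camera adjusted p = 1.10e-09; adjusted p = 0.235 with an estimated correlation; fry adjusted p = 0.0111). The list holds 14 genes, and only these 7 passed the filter on low counts. Adjusted over the list alone, 6 of the 7 rose. S100a9, a calcium-binding protein abundant in neutrophils and also made by stressed keratinocytes (ENSMUSG00000056071, chromosome 3, 90692632 to 90695721, minus strand), stood at 3.63 ± 1.44 CPM at 9 months and 23.8 ± 12 at 24 months, a log2 fold change of 2.71 ± 0.39 (SE, n = 5 each; edgeR adjusted p = 0.0909). The receptors Cxcr2 and Csf3r rose by 2.74 and 1.95, and the collagenase Mmp8 by 2.27, adjusted over the list alone, each with all 5 older mice above all 5 younger ones. Cxcr2 and Mmp8 were near the floor in the young mice, at 0.13 to 0.39 and 0.13 to 0.23 CPM. In the older mice they stood at 0.76 to 2.70 and 0.41 to 1.65 CPM. Red blood cell genes, which mark blood in the tissue, had a median of 0.67 and were not called (camera adjusted p = 0.404); without 24 months replicates 1 and 2 they were called higher, with a median of 0.81 (adjusted p = 0.000186). Mast cell genes had a median of 0.43, and 5 of 13 rose when adjusted over the list alone (camera adjusted p = 1.08e-06; adjusted p = 0.314 with an estimated correlation). Among them Hdc, which makes histamine, rose by 1.87, and the tryptase Tpsab1 by 1.97; without the 9 months replicates 4 and 5, 2 members rose.

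**Figure D1:**
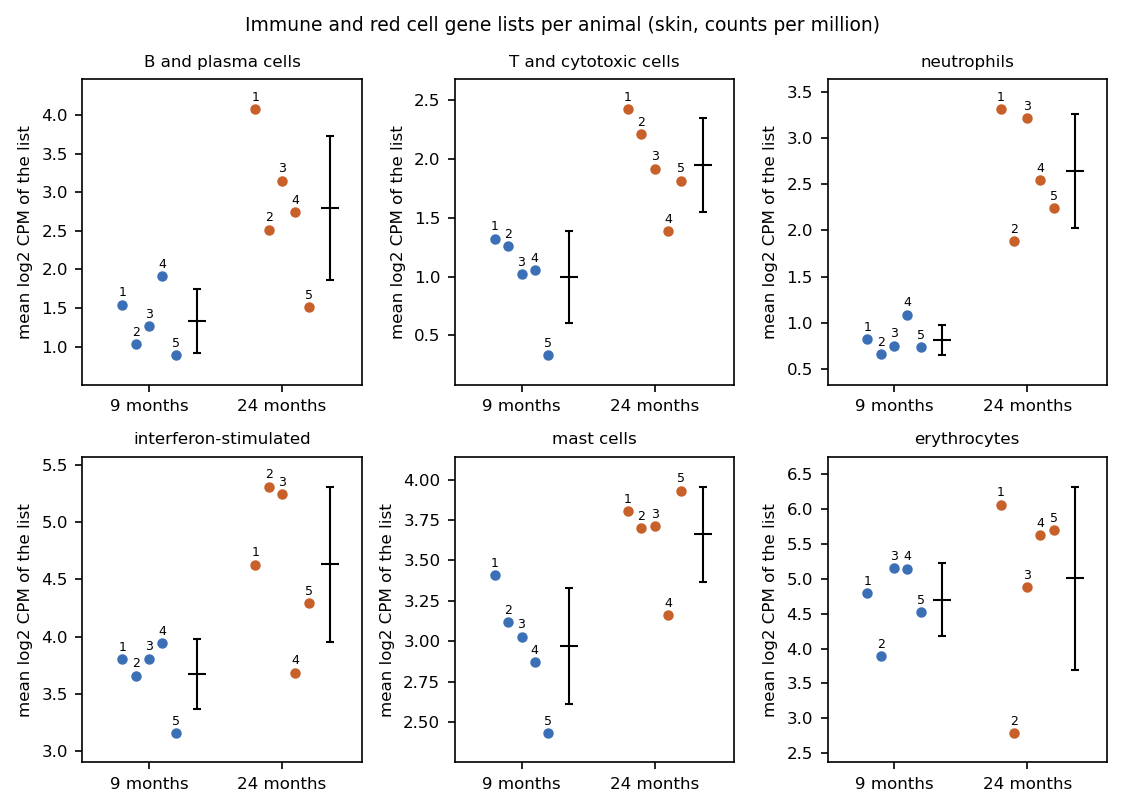
Mean log2 CPM of 6 gene lists in each mouse, at 9 months (blue) and 24 months (orange); numbers are replicates, and the black mark and bars are the mean ± SD of 5 mice. All 5 older mice lie above all 5 younger ones for the neutrophil and T cell lists, whereas the ages overlap for red blood cell genes.

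All 33 interferon-stimulated genes had positive fold changes, with a median of 1.04, and 25 rose when adjusted over the list alone (camera adjusted p = 6.17e-17; adjusted p = 0.314 with an estimated correlation). Iigp1 rose by 2.26, Igtp by 1.62, Zbp1 by 1.6 and Irgm1 by 1.51; 3 of these encode interferon-induced GTPases, and Zbp1 encodes a nucleic acid sensor. The list mean of 24 months replicate 4, at 3.69, lay within the 9 months range of 3.16 to 3.94. Without the 9 months replicates 4 and 5, the median was 0.95 and 0 members passed over the list alone. Without 24 months replicates 1 and 2, the median was 0.80 and 5 members passed. The camera call held in both cases (adjusted p = 1.8e-11 and 1.27e-12). Antigen presentation genes were higher too, with medians of 0.54 for class I and 0.44 for class II, and all 17 and all 12 members positive. Camera gave adjusted p = 4.56e-07 and 5.85e-05, and adjusted p = 0.42 and 0.359 with an estimated correlation. Adjusted over the list alone, 2 class I genes rose, H2-Q6 by 1.05 and H2-Q4 by 0.96, and 0 class II genes; Ciita, the class II transactivator, had a log2 fold change of 0.74 ± 0.23 (SE). With 9 months replicates 4 and 5 left out, the medians were 0.27 for class I and 0.21 for class II, and with 24 months replicates 1 and 2 left out 0.18 and 0.41; in neither case did a class I gene rise over the list alone.

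Macrophage and monocyte genes had a median of 0.36 (camera adjusted p = 0.000794; adjusted p = 0.624 with an estimated correlation), and 2 of 30 rose when adjusted over the list alone, the chemokine Ccl8 by 1.21 and Mpeg1, a pore-forming protein of phagocytes, by 1.35. Langerhans and dendritic cell genes had a median of 0.37 and 3 of 14 rose, Cd86, Cd83 and Ccr7, all linked to dendritic cell activation (camera adjusted p = 0.00233; adjusted p = 0.444 with an estimated correlation). Cytokines and chemokines had a median of 0.54 and 2 of 29 rose, Ccl8 again and Cxcl13, which attracts B cells (camera adjusted p = 0.000273; adjusted p = 0.444 with an estimated correlation). Cxcl13 reached 162 CPM in 24 months replicate 1 and 74.9 in replicate 2, against at most 15.7 CPM in each other library. Complement genes had a median of 0.35 and 0 of 21 rose over the list alone (camera adjusted p = 0.00195; adjusted p = 0.471 with an estimated correlation). C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882, minus strand) stood at 337 ± 59.1 and 476 ± 87.2 CPM (edgeR adjusted p = 0.237). Without the 9 months replicates 4 and 5, the camera calls for complement, cytokines, dendritic cells and class II ended, at adjusted p = 0.11, 0.129, 0.144 and 0.0523, and over the list alone 0 macrophage, dendritic cell or cytokine genes rose. The dendritic cell median was 0.21, that of complement 0.17 and that of cytokines 0.40. Macrophage genes had a median of 0.31 there, and their call held (camera adjusted p = 0.0262). Without 24 months replicates 1 and 2, 0 dendritic cell genes rose and the macrophage median was 0.58, with 6 members rising. Without 24 months replicate 3 the camera calls for macrophages and monocytes and for complement ended, at 0.0975 and 0.0675. With the growing-hair score as a covariate, the camera calls for mast cells, macrophages, dendritic cells, both antigen presentation lists, complement and cytokines ended, at adjusted p from 0.249 to 0.819.

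Genes of the hair shaft and inner root sheath, most of which are made mainly while a hair grows, gave the largest difference. All 38 tested members were lower at 24 months, with a median log2 fold change of -7.13, and all 38 fell when adjusted over the list alone (camera adjusted p = 8.76e-22; adjusted p = 0.346 with an estimated correlation). The difference came mainly from 2 libraries: the list mean was 7.92 and 9.09 log2 CPM in 9 months replicates 4 and 5, 0.74, 3.23 and 3.11 in 9 months replicates 1 to 3, and 0.29 to 2.02 in the older mice. The inner root sheath keratin gene Krt73 stood at 363 and 959 CPM in those 2 libraries, at 0.952, 10.4 and 8.98 CPM in the other 3 young mice, and at 0.803 to 2.22 CPM in the older ones. Krt26 and Krt72, further root sheath keratins, and Krtap15, a hair shaft protein, had log2 fold changes of -7.70 ± 1.87, -7.75 ± 1.88 and -7.84 ± 1.88 (SE). Without those 2 libraries the median was -1.92 and 23 of 38 fell over the list alone.

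Genes of cell division and of pigment cells were lower at 24 months and were highest in the same 2 libraries. All 45 cell cycle genes had negative fold changes, with a median of -0.93, and 31 fell over the list alone (camera adjusted p = 7.74e-22; adjusted p = 0.314 with an estimated correlation). Birc5, Cdca8 and Melk, all needed for mitosis or induced in dividing cells, fell, with log2 fold changes of -1.24, -1.26 and -1.33. The list mean of every 24 months mouse lay below that of every 9 months mouse (two-sided exact permutation p = 0.00794, 0.059 adjusted over the lists). Without the 9 months replicates 4 and 5 the median was -0.40 and 0 fell, and the camera call held (adjusted p = 1.23e-10). Melanocyte genes had a median of -2.27 over 10 members and 6 fell, among them Mlana at -1.96, Pmel at -2.88 and Tyrp1 at -4.33 (camera adjusted p = 0.000555; adjusted p = 0.444 with an estimated correlation). Without those 2 libraries the median was -0.15, 0 members fell, and the camera call ended (adjusted p = 0.324). Genes of follicle stem cells and the resting follicle had a median of -0.44, with Fgf5, which ends hair growth, at -4.54 ± 1.27 and Lgr5, a stem cell receptor, at -1.13 ± 0.37 (SE). Wnt, BMP and FGF signals of the hair cycle had a median of -0.48, with Wnt5a at -1.13 ± 0.35 and Corin, a protease of the dermal papilla, at -2.68 ± 0.87 (SE). Both lists were called by camera (adjusted p = 0.000227 and 5.85e-05; adjusted p = 0.314 and 0.235 with an estimated correlation), and 0 members of either passed over the list alone. Fgf5 stood at 4.13 and 21.5 CPM in 9 months replicates 4 and 5 and at 0.0961 to 0.498 CPM in the other 8 libraries, and Corin at 4.47 and 13.7 against 0.337 to 1.18 CPM. Without those 2 libraries the log2 fold changes were -0.68 for Fgf5, -0.46 for Lgr5, -0.46 for Wnt5a and -0.13 for Corin. Both camera calls held there, with list medians of -0.36 and -0.34 (adjusted p = 0.00254 and 0.000138). With all libraries, every 24 months mouse lay below every 9 months mouse in both list means (two-sided exact permutation p = 0.00794, 0.059 adjusted over the lists). With the growing-hair score as a covariate Fgf5 and Corin turned to 0.29 and 0.33, and the camera call for follicle stem cells ended (adjusted p = 0.249).

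**Figure D2:**
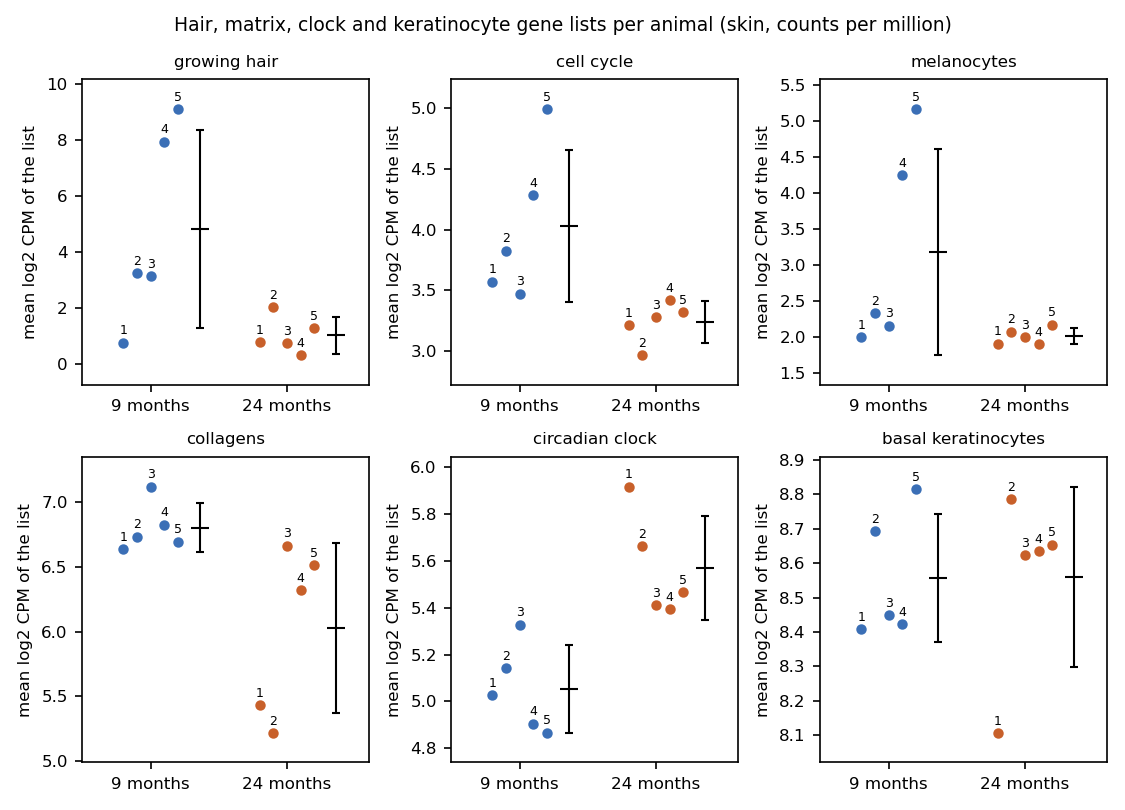
Mean log2 CPM of 6 gene lists in each mouse, at 9 months (blue) and 24 months (orange); numbers are replicates, and the black mark and bars are the mean ± SD of 5 mice. Replicates 4 and 5 at 9 months stand apart for growing hair, cell cycle and melanocyte genes, and replicates 1 and 2 at 24 months for collagens.

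Collagens and their processing enzymes were lower at 24 months, with a median log2 fold change of -0.69 and 33 of 36 members negative (camera adjusted p = 6.63e-13; adjusted p = 0.346 with an estimated correlation). Adjusted over the list alone 0 fell in the edgeR test, 17 were lower at an unadjusted p under 0.05, and DESeq2 called 2 lower. Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042, plus strand), stood at 2519 ± 461 CPM at 9 months and 748 ± 595 at 24 months, a log2 fold change of -1.75 ± 0.63 (SE, n = 5 each; edgeR adjusted p = 0.254). The 5 older mice all lay below the 5 younger ones but were themselves divided, at 114 and 111 CPM in replicates 1 and 2 and 1192, 974 and 1347 CPM in replicates 3 to 5. White adipocyte genes were high in replicate 1, at 9.42 log2 CPM, but not in replicate 2, at 7.21, within the range of the 8 other libraries, 6.78 to 7.77. Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706, plus strand) stood at 2076 ± 349 and 726 ± 557 CPM (edgeR adjusted p = 0.264). Sparc, a collagen-binding matrix protein, and Fkbp10, a collagen chaperone, had log2 fold changes of -1.29 ± 0.33 and -0.69 ± 0.22 (SE). Without 24 months replicates 1 and 2 the list median was -0.31 and 4 members fell over the list alone. Elastic fibre genes had a median of -0.34 and 3 of 17 fell, Mfap2 at -0.80, Mfap4 at -1.39 and Fbn2 at -1.4 (camera adjusted p = 5.85e-05; adjusted p = 0.403 with an estimated correlation). That call ended without 24 months replicates 1 and 2 (adjusted p = 0.37). Basement membrane genes and matrix metalloproteinases were not called, with medians of 0.07 and -0.01 and means of -0.13 and 0.14.

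Circadian clock genes had a median log2 fold change of 0.46, and 7 of 18 rose over the list alone (camera adjusted p = 3.25e-05; adjusted p = 0.235 with an estimated correlation). The list mean of every 24 months mouse lay above that of every 9 months mouse. The period genes Per1 and Per2 rose by 1.4 and 1.75, the output transcription factor Dbp by 1.51 and the clock repressor Ciart by 1.03 on the log2 scale. Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960, plus strand) stood at 57.3 ± 14 CPM at 9 months and 151 ± 49.1 at 24 months (edgeR adjusted p = 0.142). Without the 9 months replicates 4 and 5, 2 members rose with a list median of 0.30. Without 24 months replicates 1 and 2, 1 did with a median of 0.26. The camera call held in both cases (adjusted p = 0.00473 and 0.00026) but ended with the growing-hair score as a covariate (adjusted p = 0.0603). Glucocorticoid-responsive genes had a median of 0.37, and 3 of 16 rose, Per1 as above, the co-chaperone gene Fkbp5 by 1.22 and the transcription factor gene Klf9 by 0.77 (camera adjusted p = 0.00106; adjusted p = 0.235 with an estimated correlation). Immediate early genes, which respond to handling, were not called as a list (camera adjusted p = 0.679), and their members went both ways: over the list alone Nr4a3, Fosl1 and Myc rose, by 2.93, 2.83 and 0.87, and Fos and Jun fell, at -2.90 and -0.55; Fosl1 was named after its values were seen. Nr4a3 stood at 45.3 and 89.3 CPM in 24 months replicates 3 and 5, at 5.33, 5.92 and 8.79 CPM in the other 3 older mice and at 2.86 to 5.94 CPM in the young ones; leaving out 24 months replicate 5, the log2 fold change of Nr4a3 was 2.01. Without the 9 months replicates 4 and 5 this list was called lower (adjusted p = 0.00476). Fos stood at 582, 146 and 282 CPM in 9 months replicates 1 to 3 and at 22.5 to 34.1 CPM in each of the 7 other libraries. It was the 1 gene called lower without the 9 months replicates 4 and 5 and with the growing-hair score as a covariate (adjusted p = 0.0374 and 0.000634 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

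The list of senescence genes was not called, with a median of -0.18, a mean of 0.07 and camera adjusted p = 0.299. Cdkn2a, which encodes the cell cycle inhibitor p16 (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653, minus strand), stood at 0.601 ± 0.274 CPM at 9 months and 1.46 ± 0.412 at 24 months. The ages did not overlap, but narrowly and near the floor, at 0.313 to 0.931 CPM in the young mice and 1 to 2 CPM in the older ones. Its log2 fold change was 1.30 ± 0.34 (SE, n = 5 each; edgeR adjusted p = 0.163; 0.0646 adjusted over the list alone). Cdkn1a, which encodes the inhibitor p21, stood at 254 ± 26.4 and 215 ± 29.1 CPM (edgeR adjusted p = 0.508), and the p53 target list had a median of -0.14 (camera adjusted p = 0.356). Eda2r, a p53 target, had a log2 fold change of 0.70 ± 0.21 (SE).

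In the epidermis, basal keratinocyte genes had a median log2 fold change of -0.04 over 12 members and were not called. Krt14, the basal keratin (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548, minus strand), stood at 1928 ± 324 and 1808 ± 459 CPM (edgeR adjusted p = 0.915), and the sign of its difference depended on single libraries. Cornified envelope genes had a median of -0.27, with Ivl and Cnfn at -0.74 ± 0.21 and -1.04 ± 0.30 (SE) and 0 of 36 members passing over the list alone (camera adjusted p = 0.00655; adjusted p = 0.696 with an estimated correlation). That call ended without 9 months replicate 1, 9 months replicate 2 or 24 months replicate 1, at adjusted p = 0.11, 0.11 and 0.21; leaving out 9 months replicates 4 and 5, it held, with a median of -0.47 (adjusted p = 2.69e-09). All 25 cholesterol synthesis genes were negative, with a median of -0.24 and 0 passing over the list alone (camera adjusted p = 2.34e-05; adjusted p = 0.235 with an estimated correlation); Sqle, an epoxidase of the pathway, stood at -0.35 ± 0.12 (SE).

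Nuclear-encoded respiratory chain genes had a median of -0.27, with 44 of 45 members negative (camera adjusted p = 0.00148; adjusted p = 0.851 with an estimated correlation). Without 9 months replicate 1, where the list was highest at 8.14 log2 CPM, the direction turned and the adjusted p was 0.961. Heat shock genes and replication-dependent histones had medians of -0.22 and -0.58 (camera adjusted p = 0.016 and 0.0354; adjusted p = 0.346 for both with an estimated correlation), with 0 of 15 and 1 of 5 members falling over the list alone. The heat shock call ended without 24 months replicate 1 (adjusted p = 0.18), and the histone call without any 1 of 5 libraries. The 27 other lists were not called. Among them, white adipocyte genes had a median of 0.72, and Adipoq, a fat cell hormone, stood at 270 ± 77.8 and 401 ± 383 CPM (edgeR adjusted p = 0.681). Skeletal muscle genes had a median of -0.18, with Acta1, the muscle actin, at 11430 ± 4082 and 9845 ± 2391 CPM (edgeR adjusted p = 0.832). Vascular and lymphatic endothelium, smooth muscle, nerve and sebaceous gland genes had medians of 0.15, 0.16, -0.16, -0.03 and 0.09; for nerve the mean was 0.03. Without 24 months replicates 1 and 2, white adipocyte genes were called lower, with a median of -0.23 (adjusted p = 0.00897), and lymphatic endothelium genes higher, with a median of 0.30 (adjusted p = 0.0304). Skeletal muscle and smooth muscle genes were called lower without the 9 months replicates 4 and 5, with medians of -0.39 and -0.27 (adjusted p = 0.0125 and 0.00113).

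**Figure D3:**
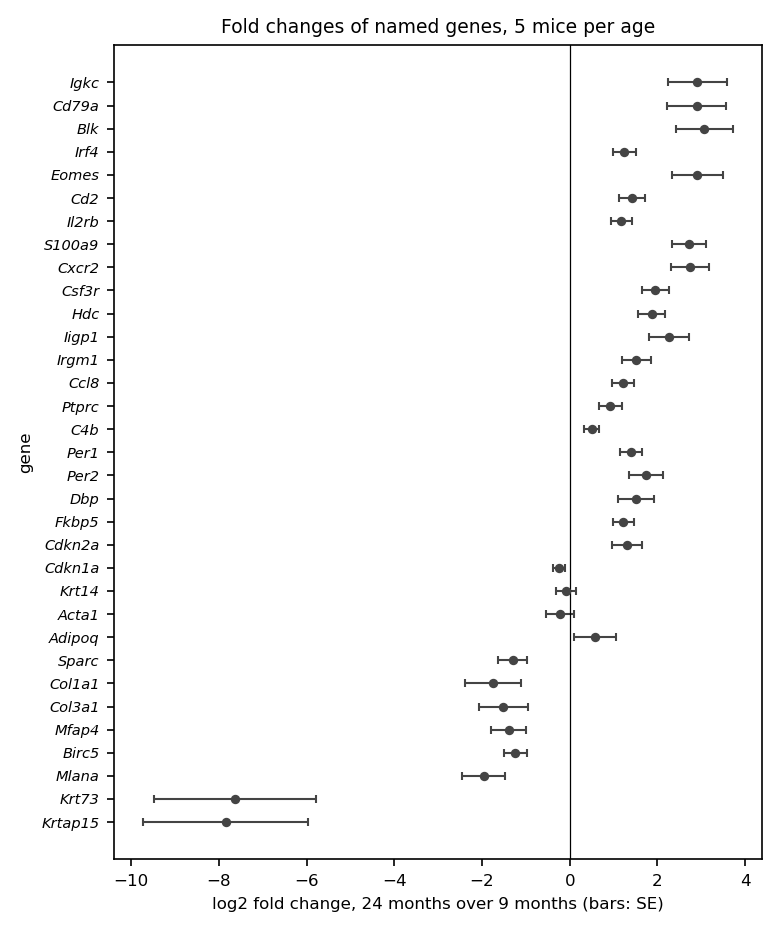
Log2 fold change of 33 named genes, 24 months over 9 months, with bars for the SE of the edgeR fit to 5 mice per age. Immune and clock genes lie to the right of 0 and matrix, cell cycle, pigment and hair genes to the left; none passed the adjustment over all genes tested.

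The mice also differed from each other within an age. The mean distance of a mouse from the centre of its group was 1.52 ± 0.568 log2 units at 9 months and 0.95 ± 0.198 at 24 months (SD, n = 5 each), a difference of -0.57 that missed the threshold of a two-sided exact permutation test (p = 0.0714). These distances cover the 1000 genes most variable within groups. Over all genes tested the difference was -0.12 (p = 0.246, exact permutation). The mice farthest from their centre were 9 months replicates 1, 5 and 4, at 2.22, 1.98 and 1.43, and the difference was -0.32 without 9 months replicate 1 and -0.30 without 9 months replicate 5 (p = 0.0873 and 0.373, exact permutation). It passed without 9 months replicate 2, 9 months replicate 3 or 24 months replicate 1 (p = 0.0159, 0.0317 and 0.0397, exact permutation). Principal components were taken from another set, the 1000 genes most variable over all libraries whatever their age. The first component held 59.8% of their variance and set apart 9 months replicates 4 and 5, at 61.1 and 82, from the other libraries, at -36.2 to 5.16. The second held 14.5% and set apart 9 months replicate 1, at -50.1, from the others, at -8.57 to 24.6. Without 9 months replicates 4 and 5 the difference in spread was -0.01 (p = 0.911, exact permutation).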

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

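The comparisons with other splits of the libraries and the thinning to equal depth were planned before their results were seen; every other test in this part was chosen afterwards. In each group of 5 libraries, the gap between the highest or lowest value and its nearest neighbour was divided by the range, and 0.71 was the critical value. Chance gives about 1 in 20 such groups, or 12.4 of the 248 looked at, and 9 passed. That expectation is rough, since lists and genes of the same libraries are not independent. Many of the genes were also picked for a small p between the ages. This count therefore does not settle whether such libraries are more frequent than chance would give.

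24 months replicate 1 accounted for 5 of the 9. It was low for follicle stem cell genes, at 4.15 log2 CPM against 4.7 to 4.89 in the other older mice (ratio 0.752), and for basal keratinocyte genes, at 8.11 against 8.62 to 8.78 (0.762). It was also low for Krt14, at 9.99 against 10.9 to 11.1 (0.799), and for Ivl, at 5.24 against 6.05 to 6.32 (0.753), and high for Irf4, at 6.3 against 5.03 to 5.28 (0.806). 24 months replicate 2 was low for replication-dependent histones, at 1.79 against 2.17 to 2.31 (0.739), and 24 months replicate 4 for Hdc, at 2.75 against 4 to 4.28 (0.818). 9 months replicate 1 was high for ribosomal protein genes, at 7.05 against 6.14 to 6.3 (0.817), and low for sebaceous gland genes, at 5.04 against 5.28 to 5.38 (0.719).

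The counts were set against other splits of the 10 libraries into 5 and 5. For the 0 genes called by edgeR's quasi-likelihood test, against 2308 at an unadjusted p under 0.05 and 916 by DESeq2, the comparison says nothing, since each of the 100 splits must give at least 0 genes; all 100 did, and the highest other value was 3. For the 2308 genes at an unadjusted p under 0.05, 2 of 100 splits gave as many, the real one included. So large a count was thus uncommon, but a split that mixed the ages gave more, and chance is not excluded. That highest other value was 2386, from a split that set 9 months replicate 1 with 24 months replicates 1, 2, 3 and 5. For the 916 genes called by DESeq2, 1 of 60 splits gave as many, the real one itself, and the highest other was 600. Both counts depended on 9 months replicates 4 and 5, which points to a structure of the samples. Where these fell on the same side, as in the real split, the other splits had medians of 1368 genes at an unadjusted p under 0.05 and 205 by DESeq2; where they were parted the medians were 525 and 1. Among the splits that kept them together, 2 of 46 and 1 of 25 gave as many genes as the real one, itself included. With so few such splits, chance is not excluded for either count. For the 25 gene lists called by camera with the preset correlation, 13 of 100 splits gave as many, the highest other was 28 and the median of the others was 19, so chance cannot be excluded for the number of lists.

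Growing-hair genes stood apart in 9 months replicates 4 and 5, with a gap of 4.70 log2 units between the lower of these libraries and the highest of the other 8. Depth is argued against, since 9 months replicate 4, at 38.99 M, was no deeper than 24 months replicates 3 and 5, at 40.77 and 39.05 M. The gap was 4.69 after every library was thinned to 29.3 M counts. That test could hardly have come out otherwise, because CPM are already scaled for depth. Follicles in the growth phase in those pieces of skin are a candidate explanation: 48 of the 55 tested melanocyte and cell cycle genes, or 87.3%, were higher in both libraries than in each of the other 8, against 8.52% of genes outside the lists, and none of the 55 is a hair shaft gene. Age, the body site and the moment of sampling within the hair cycle remain open and were not tested.

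Immune lists were higher at 24 months, and blood left in the tissue was examined as a cause for the neutrophil list only. The neutrophil list minus the red blood cell list was -3.89 ± 0.427 at 9 months and -2.37 ± 1.05 at 24 months, a difference of 1.52 (two-sided exact permutation p = 0.0159). Neutrophil genes thus rose more than red cell genes, which argues against blood of unchanged composition as the whole cause for that list. The ratio of neutrophil to red cell RNA in blood was not measured at either age, and no other immune list was tested. Blood therefore stays open as a cause for the immune lists, and red cell genes were called higher without 24 months replicates 1 and 2. A smaller share of follicle cells would raise the genes of every other cell type alike. Flat values of 4 other lists argue against it as the whole cause of the immune difference, for those cell types only. The mean of 12 immune lists minus that of 4 lists of other non-follicle cells differed by 0.746 (p = 0.00794 by the same exact permutation test, the smallest it can give). The 4 other lists themselves differed by -0.01 (p = 0.937, exact permutation) and the immune lists by 0.735. The first p therefore mostly restates the immune rise. The 4 lists, of vascular, smooth muscle, nerve and skeletal muscle genes, were chosen after their values were seen. Among non-follicle lists left out, medians were 0.72 for white adipocytes, 0.67 for red cells, 0.21 for brown adipocytes and -0.28 for cartilage. None of these was called with all libraries. A smaller share of follicle cells may still play a part. The growing-hair covariate ended 7 immune list calls, but that score itself was 4.82 log2 CPM at 9 months and 1.01 at 24 months. The covariate can therefore take out part of any age difference, so the ended calls do not decide this. Without 9 months replicates 4 and 5, medians for class I, class II, complement and dendritic cells were 0.27, 0.21, 0.17 and 0.21. With all libraries they were 0.54, 0.44, 0.35 and 0.37. Medians for mast cells, macrophages and cytokines, also among the 7, moved less, to 0.36, 0.31 and 0.40 from 0.43, 0.36 and 0.54. B cells, neutrophils and interferon genes changed little, at 2.23, 2.2 and 0.95 against 2.3, 2.26 and 1.04. T cells stood at 0.61 against 0.77, and gamma-delta T cells at 0.004 against 0.14. Age remains open as an untested explanation, as do housing and infection, on which the labels used here are silent.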

How the results depend on the processing

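Alternatives chosen after seeing the data were leaving out 9 months replicates 4 and 5 together, with or without the muscle covariate, leaving out 24 months replicates 1 and 2 with or without 9 months replicate 1, the rescaled RPKM values and the permutation of list means. No paired analysis was possible because the groups share no replicate numbers in the labels. The edgeR quasi-likelihood test called 0 genes in each direction, with 2308 at an unadjusted p under 0.05. DESeq2 called 433 higher and 483 lower, limma with quality weights 3 higher, the test with no filter on low counts 1 higher (Stfa2l1), log2(RPKM + 0.1) 2 higher as deposited and 2 with own totals (Stfa2l1 and Gm24401 in both), and 3 higher (Gm12587 besides) and 1 lower (Gm16399) with no filter. With the growing-hair covariate, and again without 9 months replicates 4 and 5, 1 gene was lower, Fos in both. Leaving out each library in turn gave 0 to 8 genes higher, the 8 without 24 months replicate 4, among them Hdc, Ccl8 and Iigp1. limma-voom, other scalings and the remaining settings gave 0 and 0. Genes named here outside the rule were chosen after their values were seen.

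Of the 25 list calls, 0 remained with an estimated correlation, 1 with fry and 0 by exact permutation, 13 with the growing-hair covariate and 20 without 9 months replicates 4 and 5. Leaving out 1 library kept 22 to 25. The melanocyte list turned upward with the growing-hair covariate (adjusted p = 0.184), and the respiratory chain list turned upward without 9 months replicate 1, with adjusted p from 6.95e-09 to 0.961 over the libraries left out. The difference in spread was -0.77 to -0.30 over the libraries left out, and that in library size -4.40 to 2.27 M. The log2 fold change of Krt14 was -0.165 to 0.0578 over the libraries left out, 0.036 with quality weights and 0.041 without 24 months replicates 1 and 2. That of Adipoq was -0.22 to 0.80, -0.14 and -0.27 in the same order. With the growing-hair covariate Fgf5 was 0.29, Corin 0.33 and Trpm1 0.69. Among values of named genes under alternatives, 1988 kept direction and side of the threshold, 62 passed it and 10 turned direction. No gene was called in the main test, so keeping the side means only that a gene stayed uncalled. Of the 62 that passed, 54 came from DESeq2. For results that changed, the cause was not tested, except that the growing-hair covariate removes differences that follow hair growth by construction. Depth limits genes near the filter, and the simulated test, with genes drawn independently, found 33 of 67 changes of 2-fold.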

Other observations

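The tests of clock genes in this part were chosen after the values had been seen. Some gene groups of the skin not described so far differed little: barrier lipid and ceramide genes had a median log2 fold change of -0.06 over 21 members, glycolysis genes -0.07 over 20, ribosomal protein genes -0.08 over 37 and chaperones of the endoplasmic reticulum -0.12 over 25. None of these 4 lists was called by camera with all 10 libraries, and glycolysis was called lower without 9 months replicates 4 and 5 (adjusted p = 0.0167). Cartilage, brown adipocyte and nuclear-retained RNA lists had larger medians, -0.28, 0.21 and 0.29, and were not called by camera either. Antioxidant genes had a median of -0.04, and 1 of 24, Gpx2, a glutathione peroxidase, fell when adjusted over the list alone. Gpx2 stood at 6.42 and 17.2 CPM in 9 months replicates 4 and 5 and at 0.771 to 5.39 CPM in the other 8 libraries, and with those 2 left out 0 members fell. The wound-type keratinocyte list had a median of -0.03 over 15 members and was not called, although 2 members rose when adjusted over the list alone, S100a9 among them.

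Per1, Per2 and Fkbp5 were higher at 24 months, as were 8 clock output genes, Per2 among them, at 4.54 ± 0.310 and 5.47 ± 0.468 log2 CPM (SD, n = 5 each; two-sided exact permutation p = 0.00794, the smallest it can give). Collection of the age groups at different times of day might account for this and would lower the genes of the opposite phase. The mean of 4 of these differed by -0.179 (exact permutation p = 0.341), and by -0.0433 without 24 months replicate 1 (exact permutation p = 0.651), so the difference came mostly from that library. Time of day and age cannot be told apart by these values, since the hour of collection is not given in the sources used here. Glucocorticoid exposure stays open too, because Per1 and Fkbp5 are among its known targets and no value here separates it from the clock.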
